A study of Mus musculus with 4 samples.

How the data were processed

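Total RNA of whole E11.5 mouse mandibles was extracted with a column kit, amplified as aminoallyl RNA and coupled to Cy5, per the labels' protocols, and hybridised to one-colour arrays, 1 sample per array. The deposited table holds 1 log2 intensity per probe and array, with 2 decimals, for 29922 probes on 4 arrays and no missing value. The log base was read from the values: their maximum of 16 equals the log2 of the top of a 16-bit scanner scale. The sorted values of the 4 columns are identical (largest difference 0), so the deposited log2 values had been quantile-normalised between arrays. The scanner, background correction, probe filter and software are not given in the sources used here, and detection calls were not used here. Quantile normalisation gives all arrays the same median and range, so a change in total RNA or a shift of most genes cannot be seen. Values near 16 and below the lower quartile of 6.79 are compressed, which understates changes there. On all 4 arrays, 110 probes lay within 0.15 of the maximum. The number of arrays limits the precision, with 2 per group and 2 residual degrees of freedom.

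Probes were named from the platform's annotation. Of the 29922 probes, 21020 had 1 gene symbol, 0 had several and 8902 had none. Of the named probes, 17558 carried a current symbol, 3410 were updated through a synonym in the GRCm38.p6 RefSeq gene table and 52 kept a symbol without a match. Coordinates of the probes were not used here. Where a gene had several probes, 3566 genes in all, the probe with the highest mean over all 4 arrays stood for the gene in gene lists and gene counts. Log2 fold changes of the brightest and the second-brightest probe of these genes correlated across genes with r = 0.413, and genes are not independent replicates. Probes that read paralogs or overlapping genes cannot be told apart from the table.

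Samples were grouped by their titles as control (2 arrays) and Bmp4 overexpression (2 arrays). The number of identical columns was 0. Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, two-sided) on the deposited log2 values, with Benjamini-Hochberg adjustment over all probes. The fit had no filter on dim probes and no covariate, and its prior had 3.59 degrees of freedom. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so single genes were tested only by the fitted model. The study's threshold, a 2-fold change with p under 0.05, was applied to the unadjusted p of the same fit. Errors are SDs between arrays or standard errors of the fit, as named beside each value.

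Before the data were examined, 28 gene lists were fixed, covering BMP, FGF, WNT, Hedgehog, Notch and retinoid signalling, mandibular patterning, tooth, cartilage and bone, matrix, cell cycle, apoptosis, stress, glycolysis, other cell types, Hox genes, sex and housekeeping. They held 553 genes, of which 500 were measured, and Bmp4 was left out of all of them. The 27 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. At that setting 12 lists passed. With an estimated correlation 0 of the 27 lists passed in camera, and 22 passed in fry, which tests whether a list's own genes move one way on balance. Genes named in the text were chosen by a rule fixed at the same time: Bmp4, the 12 genes with the largest rise and the 12 with the largest fall that passed the adjusted threshold without overlap between groups, up to 4 members with the smallest p in each list, any member of the BMP response list, and any member of the sex, globin and Hox lists as checks. Bmp4 is also 1 of the 12 rises, and predicted genes were counted without being named. Further list members are named where a gene is a usual readout of its pathway or cell type, and these were chosen after their values were seen.

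The fit was tested on simulated data for the comparison of Bmp4 overexpression with control, with 200 of 29922 probes changed per run, in 20 runs. At an adjusted p of 0.05 it recovered 93.6% of changes of 2 log2 units, 30.1% of changes of 1 and 0.373% of changes of 0.5, and 5.14% of its calls were unchanged probes. At the study threshold it recovered 48.8% of changes of 1 log2 unit, with a mean of 43.5 unchanged probes passing per run. The data had 4427 probes past the adjusted threshold, which makes that threshold less strict than with 200 changed probes. The adjusted shares therefore do not carry over to the data. On 16637 simulated genes the list test called 100% of 100 lists of 20 genes shifted by 0.5 log2 units and 5% of the unchanged lists. These genes were simulated with independent errors, so the shares do not show how the list test errs on correlated genes.

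Alternatives planned in advance were quantile normalisation, median centring, log2 of the linear value plus 50, removal of probes below the lower quartile or below the median of mean intensity, a variance trend, a per-probe equal-variance test, the replicate number as a block, the mean of a gene's probes, an estimated correlation and fry for the lists, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other group. Cyclic loess, removal of genes on X and Y and removal of probes whose 2 arrays of a group differed by over 2 log2 units were added after seeing the data. Each array has its own identifier, so slide could not be used as a block, and no batch is given in the labels.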

Results

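Gene expression was measured in whole mandibles of mouse embryos at stage E11.5 with 4 one-colour microarrays labelled with Cy5. Of these, 2 arrays came from wild-type control mandibles and 2 from mandibles with conditional overexpression of Bmp4, a secreted bone morphogenetic protein (BMP), induced with doxycycline for 24 hours. Each array gave a normalised log2 intensity for 29922 probes, and the probe annotation named 16637 genes. The median log2 intensity was 7.95, the lower quartile 6.79 and the maximum 16 on each array, because the deposited values share 1 distribution. The 2 control arrays correlated across probes with r = 0.993 and the 2 Bmp4 overexpression arrays with r = 0.993, while arrays of different groups correlated with r between 0.974 and 0.981. The design implies 1 comparison, Bmp4 overexpression against control, which asks how transcription in the mandible responds to a raised BMP dose. Whether the controls also received doxycycline is not stated. An effect of the drug or of the genotype therefore cannot be told apart from one of Bmp4. The labels do not say whether arrays of 1 group came from separate embryos or litters, so the p-values measure only the spread between these samples, which may be technical.

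Bmp4 itself was 9.68-fold higher in the overexpression samples. Its single probe (mMC017480) read 12.02 ± 0.08 in controls and 15.29 ± 0.03 in overexpression samples (log2 intensity, mean ± SD, 2 arrays each). The log2 fold change was 3.28 with a standard error of 0.11 (limma, adjusted p = 0.00137). The overexpression level lay close to the top of the scale, and the part of the transcript that the probe reads is not known, so the fold of total Bmp4 RNA is uncertain.

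Across all probes, 1912 rose and 2515 fell at an adjusted p of 0.05 in limma, and 30 of each changed by at least 4-fold. At the threshold stated for the study, a 2-fold change with an unadjusted p of 0.05, 361 probes were higher and 417 lower. Counted as genes through the brightest probe of each, these were 257 higher and 291 lower genes. The study's own counts at this threshold, stated without a test, were 120 higher and 144 lower genes. Of the 129 genes with several probes whose brightest probe passed the study threshold, 108 had a second-brightest probe that moved in the same direction, 25 had one that also passed, and 0 had one that passed in the opposite direction. Leaving out control replicate 1, control replicate 2, Bmp4 overexpression replicate 1 or Bmp4 overexpression replicate 2 left 1 residual degree of freedom and 0 probes past the adjusted threshold in limma. The lowest adjusted p-values were then 0.191, 0.138, 0.170 and 0.155, and 6020, 7947, 6650 and 7363 probes had an unadjusted p under 0.05.

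The genes that rose most were led by secretin and included the transcription factor genes Gata3 and Isl1. Sct, which encodes the peptide hormone secretin, was 13.0-fold higher (log2 fold change 3.70 ± 0.10, SE). Gata3 was 12.5-fold and Gata2 6.23-fold higher. Isl1, a LIM-homeodomain factor of several neuronal and cardiac lineages, was 7.89-fold higher. Igfbp7, a secreted insulin-like growth factor binding protein, rose 7.31-fold, from 11.60 ± 0.14 to 14.47 ± 0.10 (log2 intensity, mean ± SD, 2 arrays each). Unc5b, a netrin receptor, rose 5.52-fold, and its other probe gave a log2 fold change of 2.04. Pdgfrl, which encodes a protein related to platelet-derived growth factor receptors, rose 5.64-fold, and its other probe gave a log2 fold change of 2.43. Smad6, an intracellular inhibitor of BMP signalling, rose 5.26-fold, and Col9a3, a chain of the cartilage collagen IX, rose 5.39-fold. Rgs5, a marker of pericytes, and Angpt1, a ligand of the endothelial receptor Tek, were 7.73-fold and 5.56-fold higher, from control values below the lower quartile of all probes, where the array gives little range. All of these genes had adjusted p-values between 0.00137 and 0.00395 in limma.

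The genes that fell most included the transcription factor genes Osr2, Barx1 and Shox2. Osr2, an odd-skipped-related factor required for palate growth and for the patterning of tooth rows, fell from 12.82 ± 0.14 to 9.15 ± 0.19 (log2 intensity, mean ± SD, 2 arrays each), a 12.8-fold decrease. Barx1, a homeobox gene of the molar-forming and proximal mandibular mesenchyme, was 8.85-fold lower. Shox2, a homeobox gene needed for palate and jaw joint formation, was 7.57-fold lower, and its other probe gave a log2 fold change of -2.90. Meox2, a homeobox gene of mesoderm and palate, was 7.24-fold lower, and the nuclear receptor gene Nr5a2 was 7.81-fold lower. Cbln4, a secreted protein of the cerebellin family, had the largest fall of the named genes, at 13.1-fold. Smoc1 and Smoc2, secreted matrix proteins of which Smoc1 is known as a modulator of BMP signalling, fell 7.54-fold and 7.26-fold. Cyp1b1, a cytochrome P450 enzyme, fell 6.54-fold, C1qtnf7, a secreted C1q-related protein, fell 6.45-fold, and Bnc1, a zinc finger gene, fell 6.15-fold. Pantr1, a non-coding RNA gene beside Pou3f3, fell 6.96-fold. These 12 genes had adjusted p-values between 0.00137 and 0.00235 in limma.

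**Figure D1:**
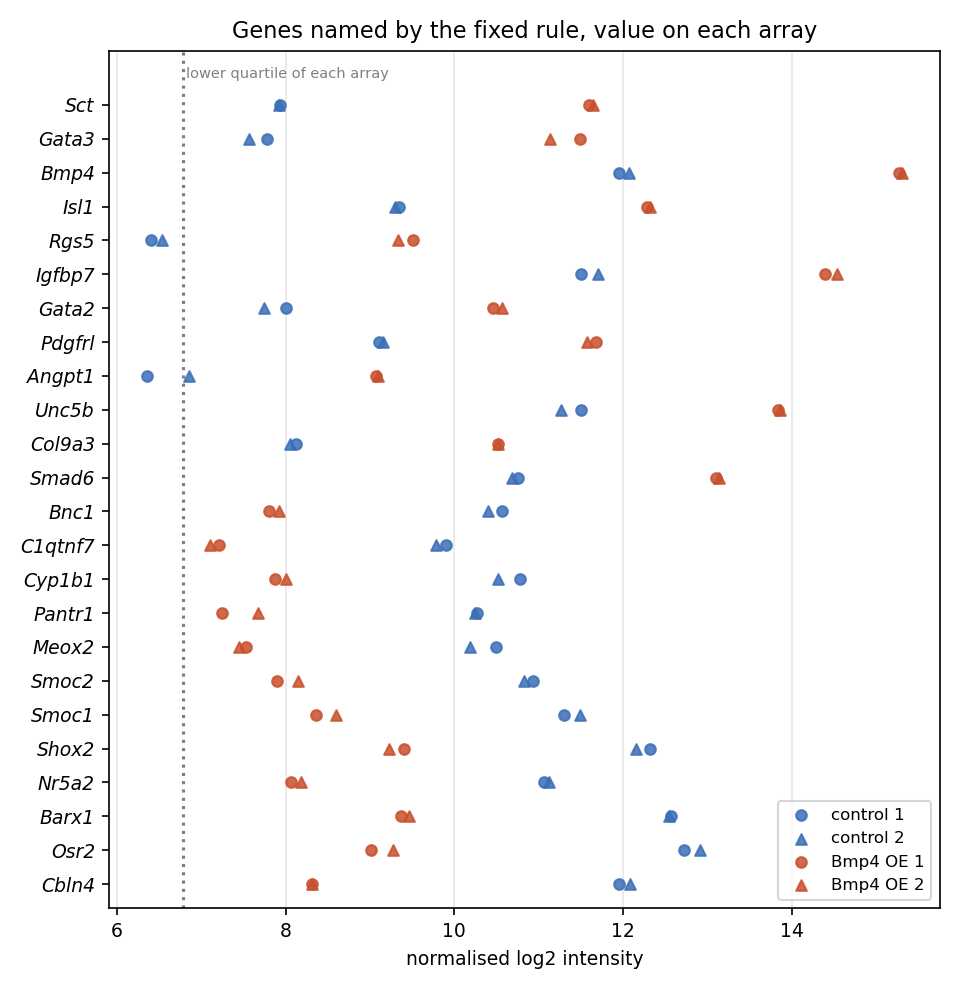
Normalised log2 intensity (x axis) of the 24 genes named by the rule fixed in advance (y axis), with 1 point per array: circles for replicate 1, triangles for replicate 2, blue for control and orange for Bmp4 overexpression. The dotted line marks the lower quartile of each array, 6.79; Bmp4 moves from 12.02 to 15.29, and the rule admitted only genes whose 2 groups of arrays do not overlap.

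Genes known to respond to BMP signalling rose together. Of 19 measured members of this list, 12 rose, 0 fell and 7 did not pass, and 14 rose when adjusted over the list alone. Alongside Smad6, Gata3 and Gata2, the extracellular BMP antagonist Nog rose 4.58-fold and the antagonist Grem1 rose 1.97-fold. The homeobox genes Msx2 and Msx1 rose 3.32-fold and 2.01-fold, and Hand1 and Tbx3, transcription factors of the distal arch, rose 3.84-fold and 1.91-fold. Id1, Id4 and Atoh8, which encode helix-loop-helix proteins, had log2 fold changes of 1.32, 1.13 and 0.81. Bambi, a decoy receptor, had a log2 fold change of 0.48 ± 0.13 (SE) and did not pass over all probes (limma, adjusted p = 0.0625). Hey1, Tbx2 and Smad9 had log2 fold changes of 0.36, 0.16 and 0.02, that of Id2 was 0.005, and Smad7 lay below the lower quartile in both groups. Id3 read 15.94 in controls and 15.99 in overexpression samples, at the top of the scale, where a rise is not measurable. The list was higher relative to other genes (camera, adjusted p = 1.22e-09; adjusted p = 0.264 with an estimated correlation).

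Among components of the BMP pathway other than Bmp4 and the response genes above, more fell than rose. Of 28 measured ligands, receptors, Smads and antagonists in this list, 0 rose, 6 fell and 22 did not pass. When adjusted over the list alone, 6 fell. The antagonist genes Nog and Grem1 and the inhibitor gene Smad6, which rose, were counted in the BMP response list instead. The share that passed, 21.4%, was near the 16.9% of all named genes (Fisher's exact test, two-sided, p = 0.458). The ligand genes Bmp7 and Bmp6 had log2 fold changes of -1.26 and -1.24, and the brightest probe of the receptor gene Bmpr1b gave -1.22, while its other 2 probes gave -0.28 and -0.34 and did not pass. The type I receptor gene Bmpr1a had a log2 fold change of 0.03 ± 0.15 (SE) and did not pass. As a whole the list did not pass against other genes (camera, adjusted p = 0.163).

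Genes of the distal mandible were higher. Of 13 measured members, 6 rose, 1 fell and 6 did not pass, and 6 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.00235, and adjusted p = 0.353 with an estimated correlation). Of the 6 that rose, 5 (Gata3, Hand1, Msx2, Msx1 and Tbx3) are also members of the BMP response list, and the other was the homeobox gene Prrx2, with a log2 fold change of 1.17. Pitx1, a homeobox gene of the mandible and hindlimb, fell, with a log2 fold change of -1.28. Hand2, a basic helix-loop-helix gene of the distal arch, had a log2 fold change of -0.02 and did not pass.

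The Dlx genes and their endothelin-related partners went both ways. Among 19 measured members, 4 rose, 7 fell and 8 did not pass, and 6 rose and 8 fell when adjusted over the list alone. Besides Barx1, the homeobox genes Pou3f3, Emx2 and Dlx1 fell, with log2 fold changes of -1.60, -1.53 and -1.34; Pou3f3 and Emx2 fell to below the lower quartile. Dlx3 rose by 0.81 on the log2 scale and Mef2c, a MADS-box factor, by 0.80, whereas Dlx5 and Dlx6 had log2 fold changes of 0.11 and -0.50 and did not pass over all probes. The list as a whole did not shift in 1 direction against other genes (camera, adjusted p = 0.163). The share that passed in either direction, 57.9%, was above the 16.9% of all named genes. Fisher's exact test, which treats genes as independent, gave an adjusted p of 0.000298 (two-sided, adjusted over the 28 lists).

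More genes of early tooth development fell than rose. Of 23 measured members, 12 fell, 4 rose and 7 did not pass, and 13 fell and 5 rose when adjusted over the list alone (camera, adjusted p = 0.00346, and adjusted p = 0.299 with an estimated correlation). Without the probes below the median intensity the list had an adjusted p of 0.0538. After Osr2 and Barx1, the largest falls were in Osr1, an odd-skipped-related factor, at -2.35 on the log2 scale, Lhx8, a LIM-homeobox gene of the oral mesenchyme, at -1.47, and Fgf10, a mesenchymal growth factor, at -1.35. The growth factor genes Fgf8 and Fgf9 of the oral epithelium fell, with log2 fold changes of -0.97 and -0.85, while the members that rose were Isl1, Msx1, Shh and Dlx2, with 0.78 for Shh. Pax9, a gene of the dental mesenchyme, had a log2 fold change of 0.01 and did not pass.

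Genes of the cartilage and bone programmes did not move as 1 block. Of 22 measured cartilage genes, 6 rose, 2 fell and 14 did not pass, and 7 rose and 4 fell when adjusted over the list alone (camera, adjusted p = 0.165). In either direction 36.4% passed, against 16.9% of all named genes (Fisher's exact test, two-sided, adjusted p = 0.0456). The 3 collagen IX genes rose, with log2 fold changes of 2.43 for Col9a3, 1.97 for Col9a1 and 1.91 for Col9a2. Sox5 rose by 1.37 and Sox9, the main transcription factor of cartilage, by 0.70 on the log2 scale. Col2a1, the major cartilage collagen, had a log2 fold change of 0.52 (limma, adjusted p = 0.0520) and Acan, the cartilage proteoglycan aggrecan, one of -0.51 (adjusted p = 0.0509), and neither passed over all probes. Among 20 bone genes, 5 fell, 3 rose and 12 did not pass, and 10 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.0412, and adjusted p = 0.398 with an estimated correlation). The falls included the matrix gene Spp1, to below the lower quartile, with a log2 fold change of -1.78, and Twist2 and Twist1, basic helix-loop-helix genes that restrain bone formation, with -1.59 and -1.19. Runx2 and Sp7, which drive bone formation, had log2 fold changes of -0.39 and -0.41 and did not pass over all probes, and Runx2 lay below the lower quartile. The bone list had an adjusted p of 0.15 without control replicate 1 and 0.0829 without Bmp4 overexpression replicate 1 (camera).

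Neural crest mesenchyme genes changed in both directions, with 6 of 20 higher, 6 lower and 8 not passing, and 6 higher and 7 lower when adjusted over the list alone (camera, adjusted p = 0.532). In either direction 60% passed, against 16.9% of all named genes (Fisher's exact test, two-sided, adjusted p = 9.93e-05). Pax3, a gene of the neural crest, fell with a log2 fold change of -1.62, and the widely expressed mesenchymal receptor gene Pdgfra had a log2 fold change of 0.03 and did not pass. Of 27 extracellular matrix genes, 7 rose, 5 fell and 15 did not pass, and 10 rose and 6 fell when adjusted over the list alone. Tgfbi and Tnc, which encode secreted matrix proteins, had log2 fold changes of 1.57 and -1.51. This list had a median log2 fold change of -0.005 and a mean of 0.10, and its test pointed up (camera, adjusted p = 0.325). The share of matrix genes that passed in either direction was 44.4% (Fisher's exact test, two-sided, adjusted p = 0.00305).

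Targets and feedback inhibitors of fibroblast growth factor (FGF) signalling were lower as a list. Of 17 measured members, 10 fell, 1 rose and 6 did not pass, and 13 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.000244, and adjusted p = 0.290 with an estimated correlation). Dusp6, a phosphatase that limits ERK signalling, had a log2 fold change of -1.89, and the ETS factor genes Etv5 and Etv4 had -1.59 and -0.88. Ccnd1, a cyclin, and Spry2 and Il17rd, inhibitors of the pathway, fell with log2 fold changes of -1.11, -1.14 and -0.92. The receptor gene Fgfr2 rose by 0.66 on the log2 scale, and Spry4 had a log2 fold change of 0.07 and did not pass. Spred2, another inhibitor, went the other way, with 1.13 at its brightest probe (limma, adjusted p = 0.0517). Its second probe gave 0.785 and passed (adjusted p = 0.0224).

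The WNT, Hedgehog, Notch and retinoid lists did not pass against other genes in camera. In either direction 41.7% of the WNT list passed in limma, against 16.9% of all named genes (Fisher's exact test, two-sided, adjusted p = 0.0104). The same test gave adjusted p-values of 0.126, 0.368 and 0.101 for the Hedgehog, Notch and retinoid lists. Of 24 WNT pathway genes, 8 fell, 2 rose and 14 did not pass, and 9 fell and 2 rose when adjusted over the list alone (camera, adjusted p = 0.0916). The secreted antagonist genes Sfrp2 and Sfrp1 had log2 fold changes of -1.98 and -1.59, while Dkk1, another antagonist, rose by 1.40 on the log2 scale; the second probe of Sfrp1 gave -0.44 and did not pass. Axin2, a common readout of the pathway, had a log2 fold change of -0.16 and did not pass. Among 14 Hedgehog pathway genes, 4 fell, 1 rose and 9 did not pass, and 4 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.434). The largest fall there was that of Osr2, also in the tooth list, and of the direct targets, Hhip fell, with a log2 fold change of -0.48, while Gli1 and Ptch1 had -0.08 and 0.44 and did not pass over all probes. Of 15 Notch pathway genes, 3 fell, 1 rose and 11 did not pass, and 3 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.298). The target gene Hey2 and the receptor gene Notch1 fell, with log2 fold changes of -1.55 and -0.77. Of 13 retinoid pathway genes, 3 fell, 2 rose and 8 did not pass, and 3 fell and 2 rose when adjusted over the list alone (camera, adjusted p = 0.200). Cyp26a1, which degrades retinoic acid, and Aldh1a2, which makes it, both had a log2 fold change of -2.03, and the binding protein gene Crabp2 had -1.25.

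Cell cycle genes fell together. Of 28 measured members, 24 fell, 0 rose and 4 did not pass, and 26 fell when adjusted over the list alone (camera, adjusted p = 5.74e-14, and adjusted p = 0.264 with an estimated correlation). The median log2 fold change of the list was -0.81. Ccne1, a cyclin of S-phase entry, had a log2 fold change of -1.58, and the mitotic kinase genes Bub1, Aurka and Plk1 had -1.36, -1.14 and -1.06. Birc5, which encodes survivin, had -1.26 at its brightest probe and -0.98 and -1.96 at the other two. The proliferation marker Mki67 had a log2 fold change of -0.76, and its other 2 probes gave -0.93, and -0.12 without passing. Of 18 genes of the p53 and apoptosis list, 3 rose, 1 fell and 14 did not pass, and 4 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.133). The genes that rose were the stress-response genes Gadd45b and Gadd45g and the cell cycle inhibitor Cdkn1a, by 2.05, 1.74 and 0.97 on the log2 scale. The proapoptotic p53 targets Bbc3 and Pmaip1 had log2 fold changes of -0.39 and -0.34 and did not pass.

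As lists, macrophage, muscle, neuron and epithelial markers were higher relative to other genes. The share past the adjusted threshold in either direction was 41.2%, 24.1%, 19.0% and 45.5% in these lists, against 16.9% of all named genes. The muscle and neuron shares were near that of all genes (Fisher's exact test, two-sided, p = 0.318 and 0.771). Of 17 macrophage genes, 7 rose, 0 fell and 10 did not pass, and 9 rose when adjusted over the list alone (camera, adjusted p = 2.91e-05, and adjusted p = 0.290 with an estimated correlation). The complement genes C1qb and C1qc and the surface marker Adgre1 rose by 1.25, 1.15 and 1.06 on the log2 scale, whereas Ptprc and Lyz2 lay below the lower quartile in both groups. Of 29 skeletal muscle genes, 7 rose, 0 fell and 22 did not pass, and 7 rose when adjusted over the list alone (camera, adjusted p = 0.000656, and adjusted p = 0.290 with an estimated correlation). The troponin gene Tnnt1 rose by 1.34 and the myosin gene Myl4 by 0.90, while the muscle regulators Myod1 and Myog had log2 fold changes of 0.13 and 0.02 and did not pass. Among 21 neuronal genes, 3 rose, 1 fell and 17 did not pass, and 6 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0218, and adjusted p = 0.334 with an estimated correlation). The largest rise in that list was Isl1, which is also in the tooth list, and the adjusted p was 0.0777 without Bmp4 overexpression replicate 1. Beside the macrophage, muscle and neuron lists, probes for 688 olfactory receptor genes, which are used mainly in the nose, had a median log2 fold change of 0.17, and 75.3% of them were above 0. Of 22 epithelial genes, 8 rose, 2 fell and 12 did not pass, and 9 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.00566, and adjusted p = 0.299 with an estimated correlation). The simple-epithelium keratin genes Krt8 and Krt18 rose by 1.23 and 1.20 and Cdh1, the epithelial cadherin, by 0.92, while the basal keratin genes Krt14 and Krt5 fell, with log2 fold changes of -0.79 and -0.46.

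The glial list was lower, the erythroid list was lower by a small amount, and the endothelial list did not pass. Of 15 erythroid genes, 4 fell, 0 rose and 11 did not pass, and 5 fell when adjusted over the list alone (camera, adjusted p = 0.0412, and adjusted p = 0.353 with an estimated correlation). The haem synthesis gene Alas2 had a log2 fold change of -0.59, and the embryonic globin genes Hba-x and Hbb-y lay at the top of the scale. The median of the erythroid list, -0.14, lay within the central 95% of random lists matched on brightness, -0.18 to 0.16, with 495 of 10000 as low. That list had an adjusted p of 0.124 without Bmp4 overexpression replicate 2 and 0.0944 without control replicate 1 (camera). Of 13 glial genes, 3 fell, 1 rose and 9 did not pass, and 5 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.0280, and adjusted p = 0.340 with an estimated correlation). Ednrb, Sox2 and Postn fell, with log2 fold changes of -0.91, -0.75 and -1.01, the second probe of Sox2 gave -0.37 and did not pass, and Postn is also in the bone and matrix lists. The glial list had an adjusted p of 0.0577 without control replicate 2 and 0.0545 without Bmp4 overexpression replicate 2 (camera). Of 19 endothelial genes, 2 rose, 0 fell and 17 did not pass, and 2 rose when adjusted over the list alone (camera, adjusted p = 0.0916). Ramp2 and Cldn5 rose by 1.52 and 0.56 on the log2 scale, and the junction genes Pecam1 and Cdh5 had log2 fold changes of 0.39 and -0.06 and did not pass.

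**Figure D2:**
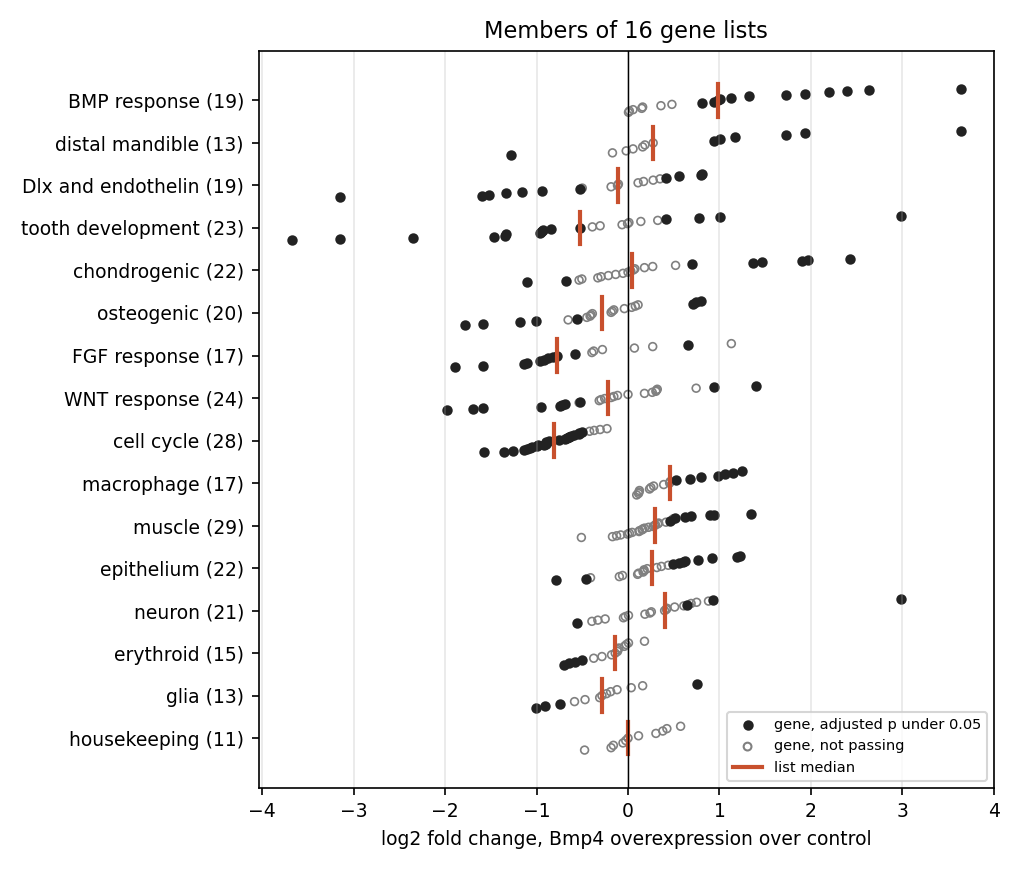
Log2 fold change of Bmp4 overexpression over control (x axis) for the measured members of 16 of the gene lists (y axis, number of measured members in brackets); filled points passed an adjusted p of 0.05 over all probes, open points did not, and the orange bar is the list median. The cell cycle list lies wholly below 0 with a median of -0.81, and the BMP response list has a median of 0.98.

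Several lists served as checks of the samples. Of 3 measured sex-linked marker genes, 2 fell, 0 rose and 1 did not pass, and 2 fell when adjusted over the list alone. The Y-linked genes Kdm5d and Eif2s3y had log2 fold changes of -1.51 and -0.93 (limma, adjusted p = 0.00347 and 0.00922), while Uty, also Y-linked, lay below the lower quartile in both groups. Without genes on X and Y, a setting added after seeing the data, 351 probes were higher and 400 lower at the study threshold. This setting only removes those probes, so it cannot show whether sex affected the remaining genes. Of 24 Hox genes, which first arch mesenchyme mostly lacks, 3 rose, 6 fell and 15 did not pass, and 3 rose and 6 fell when adjusted over the list alone (camera, adjusted p = 0.937). In either direction 37.5% passed, against 16.9% of all named genes (Fisher's exact test, two-sided, adjusted p = 0.0302), so this check does not show Hox genes unchanged. The brightest probe of Hoxc8 gave -0.59 and its other probe 0.60, and both passed in limma. The median log2 fold change of the Hox list was 0.08 and its mean -0.03, and Hoxd8 fell to below the lower quartile, with -1.53. Of 21 immediate early and stress genes, 5 rose, 1 fell and 15 did not pass, and 6 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.118), with the stress-induced factor Atf3 highest at 1.41. Of 22 genes of glycolysis and hypoxia, 4 rose, 2 fell and 16 did not pass, and 5 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.625). The hypoxia-inducible gene Egln3 rose by 1.13 on the log2 scale, and this list had a median of -0.01 and a mean of 0.06. Of 11 housekeeping genes, 0 passed in limma, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05. The log2 fold changes of the 11 ran from -0.48 for Hprt to 0.58 for Rplp0 (camera, adjusted p = 0.625). The second probe of Rplp0 gave a log2 fold change of -0.04.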

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

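Cyclic loess, the removal of genes on X and Y and the removal of probes with disagreeing arrays were chosen only after the results were seen. The 24 genes named by rule kept an adjusted p under 0.05 in 9 of the 15 alternatives to the reported limma fit, although 2 had no value without probes below the median intensity. Among the 9, quantile normalisation and median centring moved no value, because the deposited columns already share 1 distribution, and say nothing of stability. The variance trend and the settings that remove genes or probes left the fold changes of these genes in place and altered only their p-values. Their direction was no test in 14 of the 15, because genes whose groups overlap had been left out, and under cyclic loess 0 of 24 reversed. Calls ended in the equal-variance test, with the replicate block and with any array left out, while the smallest absolute log2 fold change of the 24 was 2.23 to 2.42 in these 6 settings, against 2.40 in the reported fit. Bmp4 lay between 3.22 and 3.33 on the log2 scale when each array was left out in turn, at 3.28 with the replicate block and 3.28 in the equal-variance test, and its adjusted p over all alternatives ran from 6.11e-05 to 0.191. With the replicate block, 0 probes rose and 0 fell past the adjusted threshold in limma (8724 at an unadjusted p under 0.05), and in the equal-variance test 0 and 0 (6253 unadjusted, 65 probes without spread left out), against 9868 unadjusted in the reported fit. Leaving out each array in turn gave 0 to 0 probes in either direction past the adjusted threshold, 348 to 530 higher and 391 to 496 lower probes past the study threshold, and 237 to 370 higher and 276 to 330 lower genes. Counts at the study threshold stayed within 1.5 times the reported ones. The lowest were 266 higher and 296 lower probes, with log2 of the linear value plus 50, and the equal-variance test gave 292 and 394, of which 682 in all were shared with the 778 reported. Replicate numbers are shared between groups without a stated pairing, and the deviations of same-numbered arrays correlated at -0.07 across probes. This shows no large effect shared by same-numbered arrays, but cannot tell whether the samples were paired in litter or handling. With the replicate block 351 higher and 415 lower probes passed the study threshold, and the bone list reached an adjusted p of 0.0718, the only list call that the block changed.

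The BMP response, cell cycle, FGF response, distal mandible, macrophage, muscle and epithelial lists passed under every alternative run on lists except the estimated correlation, and no list that passed changed direction. That setting ended all 12 list calls, with adjusted p-values of 0.264 (BMP response, cell cycle), 0.290 (FGF, muscle, macrophage), 0.299 (tooth, epithelium), 0.334 (neuron), 0.340 (glia), 0.353 (distal mandible, erythroid) and 0.398 (bone). It estimates the correlation from 2 residual degrees of freedom, to which camera then refers its statistic. The estimates for BMP response and cell cycle, -0.02 and -0.004, lay below the preset 0.01, so a higher correlation did not end these calls. For distal mandible and bone they lay above it, at 0.14 and 0.07. The lowest unadjusted p in camera was then 0.0123, for the cell cycle list. With fry, which does not compare a list with other genes, 10 further lists passed: WNT at 0.00841, cartilage 0.00996, matrix 0.0112, Dlx and endothelin 0.0125, Notch 0.0125, retinoid 0.0125, Hedgehog 0.0126, endothelium 0.0126, p53 0.0232 and stress 0.0367. Without probes below the lower quartile the bone and erythroid lists reached 0.0742 and 0.0826. Without those below the median, tooth reached 0.0538, glia 0.0538, bone 0.149 and erythroid 0.322. Without genes on X and Y, bone reached 0.0512, neuron 0.0505 and erythroid 0.0868, and with the mean of a gene's probes the neuron list reached 0.0608. With each array left out in turn, adjusted p ran from 0.0318 to 0.15 for bone, 0.0275 to 0.124 for erythroid, 0.0197 to 0.0777 for neuron and 0.01001 to 0.0577 for glia. Apart from the lower number of arrays or probes that some of these settings leave, the cause was not tested. Without detection calls, genes below the lower quartile cannot be called unexpressed, and the 110 probes at the top of the scale can show no rise.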

Other observations

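Tests in this part were chosen after the results were seen, except the count over splits of the arrays. Several genes that act with GATA factors in heart and arch development rose beside Gata2, Gata3 and Isl1. They were chosen after their values were seen, so their direction is a description. Gata6 rose by 2.15 on the log2 scale, Tbx20 by 2.09 from a control value below the lower quartile, Zfpm1 and Zfpm2, cofactors of GATA proteins, by 1.81 and 1.41, and Nkx2-6 by 1.66. Of 16 such genes measured, 12 rose, 0 fell and 4 did not pass in limma. Among 19 WNT ligand genes, 7 fell and 1 rose (camera, adjusted p = 0.00149, and adjusted p = 0.212 with an estimated correlation). Wnt2, Wnt9a and Wnt5a had log2 fold changes of -2.15, -1.30 and -0.75, the other probe of Wnt9a gave -0.11 and did not pass, and Wnt8b rose by 0.76. Of 14 Eph receptor genes, 4 fell and 0 rose, with Epha3 lowest at -1.32 (camera, adjusted p = 0.00637, and adjusted p = 0.212 with an estimated correlation). Among 41 collagen genes, 5 rose and 9 fell (camera, adjusted p = 0.364), and outside collagen IX, Col24a1 rose by 1.09 and Col8a1 fell, with -1.72. Of 17 Sox genes, 3 rose and 4 fell, with Sox8 highest at 1.85 (camera, adjusted p = 0.244).

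Beside the cell cycle list, 9 of 35 kinesin genes fell and 2 rose, among them the mitotic motor genes Kif11, Kif4 and Kif18b with -1.64, -1.49 and -1.48 (camera, adjusted p = 0.00664, and adjusted p = 0.235 with an estimated correlation). A bias that depends on probe brightness would move other genes of the same brightness too. Of 10000 random lists matched on mean log2 value, 0 had a median as low as that of the cell cycle list, -0.81. Among the random lists, 95% lay between -0.18 and 0.15. Cell cycle genes thus fell more than other genes of their brightness. Quantile normalisation makes such lists centre near no change in any case, so this cannot test a bias present before normalisation. Dilution by non-cycling cells of another type would lower mesenchyme genes by about as much. The median of the mesenchyme list lay 0.68 above that of the cell cycle list (-0.13 and -0.81, permutation p = 6e-05, two-sided), but its 20 members went both ways with an SD of 0.79, which keeps this explanation open. A lower rate of proliferation under Bmp4 overexpression, the biological difference that the design names, also stays open and was not tested.

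The fall of the Y-linked genes may reflect a smaller share of male tissue in the overexpression samples. If so, X-linked genes with a Y-linked partner would be higher, and the median log2 fold change of Kdm6a, Eif2s3x, Kdm5c and Ddx3x was 0.49, from 0.14 for Ddx3x to 0.81 for Kdm6a, and 117 of 10000 random lists of 4 X-linked genes had a median as high. Kdm5d and Eif2s3y fell by different amounts, -1.51 ± 0.10 and -0.93 ± 0.10 (SE), and whether a probe also reads an X-linked partner was not tested. The labels give no sex, so a contribution of the sex mix to autosomal changes cannot be told apart from the groups. If it contributed, X-linked genes could pass the adjusted threshold more often, but this need not follow. No such excess was seen, with 16.7% of 557 X-linked and 16.9% of 16030 autosomal genes passing (Fisher's exact test, two-sided, p = 0.954). Because such an excess need not follow, similar shares cannot decide whether the sex mix contributed.

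The macrophage, muscle and neuron lists were higher, and so were probes for olfactory receptor genes, of which 65 rose and 6 fell out of 688 (camera, adjusted p = 5.93e-07, but 0.304 with an estimated correlation), and 0 of 1000 lists of other genes matched on brightness had a median as high as their 0.17. A lower share of mesenchyme would raise the other cell types alike, but the means of the 7 marker lists differed (permutation p = 1e-04, the smallest that 10000 permutations can give). Members below the lower quartile in both groups or at the top of the scale were left out. The means were then 0.62 for macrophages (SD 0.37, 14 of 17 members) and -0.32 for glia (SD 0.51, 11 of 13 members). Over all members these means were 0.53 and -0.30, and 10 of the glial members in no other list had a mean of -0.25. The permutation treated genes as replicates, and markers that respond to Bmp4 would also make the lists differ. A lower share of mesenchyme therefore stays open. Of 10000 lists of all genes matched on brightness, 1 reached the macrophage median of 0.46, so macrophage genes rose more than other genes of their brightness. After quantile normalisation such lists centre near no change in any case, so this cannot test a bias present before normalisation. An upward shift shared with olfactory receptor probes is a candidate explanation for the macrophage list, and a higher share of macrophages stays open. Whether the tissue uses these receptor genes was not tested. The 15 of 17 members in brightness bins with at least 20 receptor genes had a median of 0.39 and held 6 of the 7 genes that rose. Of 10000 lists of olfactory receptor genes of the same brightness, 3775 had a median as high. Only medians were compared. Past the adjusted threshold, 7 of 17 macrophage genes rose, against 65 of 688 receptor genes. At the study threshold, 3 of 17 were higher, against 14 of 688. These counts were not matched on brightness, so whether a shared shift covers the macrophage genes that rose most was not tested. For the muscle and neuron lists this shift cannot be told apart from a higher share of these cells, because the 18 of 29 and 15 of 21 members compared, with medians of 0.17 and 0.26 against 0.29 and 0.40 for the whole lists and 8773 and 6312 of 10000 draws as high, held only 1 of 7 and 0 of 3 genes that rose.

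With 4 arrays there are 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 778 probes at the study threshold, 1 of the 3 splits gave as many, and the highest other split gave 6. Of the 778 probes, 146 have no gene symbol in the annotation used here. Single arrays stood apart at few probes: 7 probes of control replicate 1 lay over 2 log2 units above the other 3 arrays, against 2, 2 and 0 in control replicate 2 and Bmp4 overexpression replicates 1 and 2. In the same order of arrays, 2, 4, 5 and 1 probes lay over 2 log2 units below the other 3.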
